A study of Mus musculus with 12 samples.

How the data were processed

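Gene expression was measured in mouse embryonic fibroblasts (MEFs), primary cells grown from whole embryos, on 12 Agilent arrays with 1 dye (Cy3) and 100 ng of total RNA per array. The labels give 2 genotypes, wild type (WT) and Itpr2 knock-out (KO), and 2 culture ages, 3 passages (early) and 5 passages (late), with 3 replicates in each of the 4 groups. Embryos were taken at day 12.5. The design text of the series states that the fibroblasts came from 3 independent animals of each genotype. It also mentions liver tissue, which was not analysed here.

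The deposited scanner files hold, per the file headers, the intensity of each spot after the Agilent Feature Extraction software had subtracted the background and removed trends across the array, with no normalization between arrays. The file headers give version 11.5.1.1 of that software, while the submitters' processing notes give 10.7.3.1. The deposited value table of the authors holds log2 values for 22887 probes. From its values, it was scaled to the 75th percentile of each array and then centred on the mean of each probe over the 12 arrays. There, 95% of the probe means lay within 0.0001 of 0, and 3175 values were missing. The authors' filter on probes was not given in the sources used here.

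Each array carried 39429 different probes in 43020 spots, with 399 probes printed more than once. Between 23355 and 26614 probes per array, or 59.2% to 67.5%, were well above background by the scanner software's own call. The 75th percentile of the intensity lay between 568.9 and 902.5, and 0 probes were saturated. The number of arrays, 3 per group, limits the precision of every difference.

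For the main values, spots called outliers by the scanner software were left out, which numbered 100 to 212 per array. Repeated spots of a probe were averaged, intensities were taken to log2, and the 75th percentile of each array was subtracted. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 24466 probes, and 107 further probes were left out because a spot was called an outlier. Where a gene had several kept probes, the probe with the highest mean over all arrays stood for it, and other probes of a named gene were checked for the same direction. This gave 19507 genes or unnamed transcripts, of which 14577 had a gene symbol. The accession of each probe was taken from the array annotation in the files. Gene symbols came from matching it to a table of mouse genes on assembly GRCm38.p6, and probes without a match kept their annotated identifier. Of 28290 probes with a RefSeq mRNA or non-coding RNA accession, 27969 matched. That table was used for current names and for the order of neighbouring genes. The arrays were annotated on an older build, so no coordinates are given.

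Differences were tested with limma 3.58.1 in R 4.3.3. A single model with the 4 group means was fitted to all 12 arrays, and 5 contrasts were taken from it. These were KO against WT at early passage, KO against WT at late passage, late against early passage in WT, late against early passage in KO, and the difference between the last pair. The model had 8 residual degrees of freedom, and the moderated variances added 2.22 prior degrees of freedom. P-values were adjusted over all 19507 genes with the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. Log2 differences are given with the standard error (SE) of the model and rest on 3 arrays per group. The p-values rest on 1 spread between arrays per gene, pooled over the 4 groups, and not on the 2 groups compared alone. The groups differed in spread. The median SD of a gene was 0.214 in WT early, 0.141 in KO early, 0.16 in WT late and 0.0839 in KO late arrays. Where a gene was above background on 0 arrays of a group, the fold was computed against the lowest signal called above background on those arrays and is given as a lower bound ("at least"). Where it was above background on only some arrays of a group, the difference stands as measured and its size is uncertain. With 3 arrays against 3, an exact permutation of a single gene cannot give a two-sided p below 0.1.

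In all, 28 gene lists were fixed before the data were examined, together with the tests, the filters, most alternatives and the rule for naming genes. They covered calcium handling, contacts between the endoplasmic reticulum and mitochondria, p53 targets, inhibitors of cyclin-dependent kinases, secreted factors of senescent cells, cell cycle, metabolism, stress responses, matrix, interferon response, ribosome, Hox genes, markers of 9 cell types, genes near Itpr2 and sex-linked genes. Each list was tested with camera, which compares its genes with all other genes, at a preset correlation between genes of 0.01, with adjustment over the 28 lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move in 1 direction on balance, were run beside it. A list is said to be called, or not called, by camera at the preset correlation. Fry is reported only for lists that camera called, so a list not called here may still pass by fry. Members past the threshold were counted over all genes and, separately, adjusted over the list alone.

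The rule for naming genes took Itpr2 first. For each contrast it then took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, with a gene symbol and with groups that did not overlap. Overlap was not asked of the difference of passage effects. Up to 4 members of each list with the smallest p were added. Genes named outside the rule are stated as chosen after their values were seen.

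The scan, the slide and the replicate number coincided, each slide holding 1 array of every group, while the position on the slide followed the group on all 3 slides. Whether equal numbers pair the arrays of 2 groups was checked by correlating each array's deviation from its group mean. Deviations of WT early and WT late arrays of the same number correlated across genes at 0.28, 0.24 and 0.14, each the best match. Those of KO early and KO late arrays correlated at 0.030, 0.079 and -0.092. Genes are not independent replicates in such a correlation. List medians are therefore also given within each slide.

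The pipeline was tested on simulated data of 19507 genes. Noise was drawn for each gene on its own, with the pooled spread of that gene used in all 4 groups. For KO against WT at early passage it called 17 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold, 48 of 50 changed 4-fold and 50 of 50 changed 8-fold, and 3 of 19267 unchanged genes. For KO against WT at late passage the calls were 12, 39, 44 and 49 of 50, and 8 of 19267 unchanged genes. In the simulated comparison of passages in WT, the 1 shifted list of 28 was called and 0 others. The simulated genes were uncorrelated and equally variable in all groups, unlike those of the real arrays. The simulation therefore does not show how many false calls of genes or lists to expect in the real data.

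Alternatives covered quantile normalization, background correction by normexp (offset 50) followed by quantile normalization, the authors' value table, no filter or a stricter filter on dim probes, and other ways to treat several probes of a gene. Others were a replicate block, the slide as a random block, a fit of the 2 groups alone, trended and robust variances, array weights, a minimum of 2-fold, an unequal-variance test per gene, and leaving out each array in turn. The files hold no mean spot signals, so normexp was run on median signals. Chosen after the data were seen were array weights estimated gene by gene, Xist as a covariate, the mean of the macrophage list as a covariate, leaving out both KO late arrays with Xist above background, the WT arrays alone with the replicate block, and leaving out each array for the gene lists.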

Results

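Transcript levels were measured on 12 one-colour arrays of primary mouse embryonic fibroblasts, 3 each from WT and KO-labelled cultures at early passage and 3 each at late passage. Itpr2 encodes the type 2 inositol trisphosphate receptor, a calcium release channel of the endoplasmic reticulum. The series title and what is known of the study set the question of how loss of this channel alters fibroblasts as they age in culture. Between 59.2% and 67.5% of the 39429 probes were well above background on each array. Correlations between replicates of a group ran from 0.985 to 0.997. The first principal component, with 41.0% of the variance, separated early from late passage. The next one, with 19.4%, separated WT from KO-labelled arrays at late passage only. Early arrays of both genotypes overlapped on it but were spread from -6.41 to 23.5. The highest of them, KO early replicate 3, lay near the KO late arrays at 25.7 to 30.9.

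The array carries 1 kept probe for Itpr2 itself, and where it lies relative to the deleted part of the gene is not given in the sources used here. Its mean log2 signal relative to the 75th percentile was 0.95 ± 0.28 (SD, n = 3) in WT early, 1.35 ± 0.23 in KO early, 1.61 ± 0.11 in WT late and 1.76 ± 0.058 in KO late arrays. The signal was therefore not lower in KO-labelled arrays, and the probe does not check the genotype. Genes next to Itpr2 on the chromosome did separate the genotypes. Ints13, its nearest measured neighbour, which encodes a subunit of the Integrator complex, had 1.03 as its lowest value in the 6 KO-labelled arrays and 0.36 as its highest in the 6 WT arrays. Dera, an enzyme of deoxyribose phosphate breakdown from the same chromosome region, had -0.47 as its lowest KO-labelled and -1.22 as its highest WT value. Both genes were picked for this check after their values were seen.

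**Figure D1:**
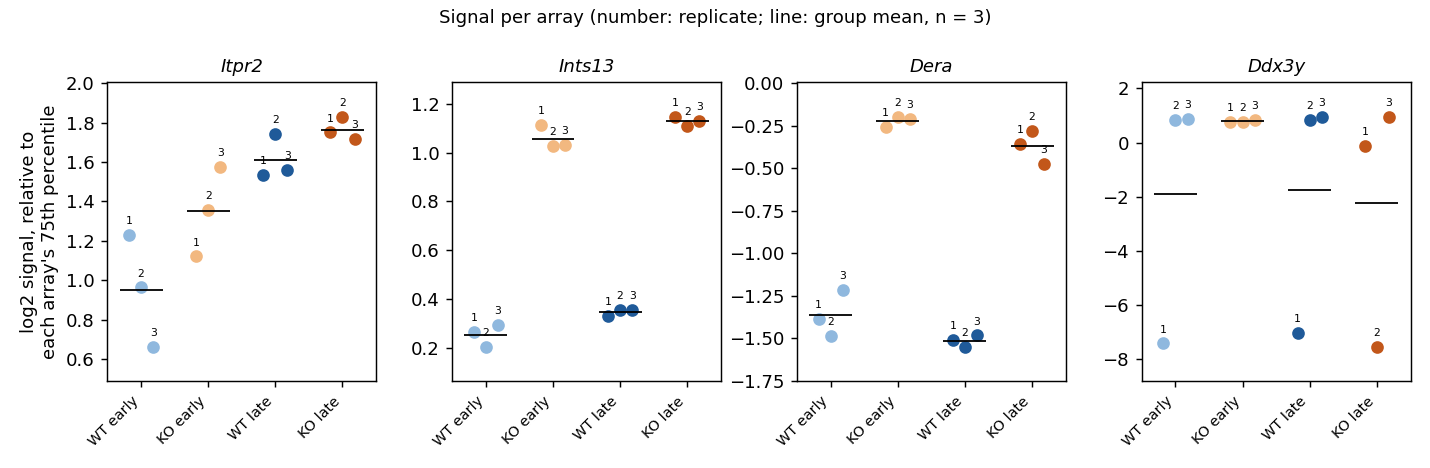
Log2 signal of Itpr2, Ints13, Dera and the Y-linked Ddx3y on each of the 12 arrays, relative to the array's 75th percentile, with replicate numbers above the points and lines at the group means. Ints13 and Dera separate KO-labelled from WT arrays with no overlap, Itpr2 does not, and Ddx3y is absent or reduced on 4 arrays.

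Sex-linked transcripts did not follow the groups. Xist, the RNA of the inactive X chromosome in females, was above background on 4 arrays, namely WT early replicate 1, WT late replicate 1, KO late replicate 1 and KO late replicate 2. Ddx3y, a Y-linked RNA helicase, was between 0.76 and 0.95 on the 8 arrays without Xist. It was -0.14 on KO late replicate 1 and below background on KO late replicate 2, while all 3 KO early arrays were in the male range. The 4 measured sex-linked genes changed in 0 of the comparisons.

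KO against WT at early passage asked how KO-labelled cultures differ from WT when young. The groups were close, with 7 of 19507 transcripts changed, 5 higher and 2 lower in KO. Dera was 2.21-fold higher, a log2 difference of 1.14 ± 0.088 (SE, n = 3 per group, adjusted p = 0.0022), and Ints13 was 1.74-fold higher, at 0.80 ± 0.067 (adjusted p = 0.0024). Mgp, matrix Gla protein, an inhibitor of calcification, was lower by a log2 difference of -1.06 ± 0.13 (adjusted p = 0.034). Pbp2, a phosphatidylethanolamine-binding protein, was at least 2.28-fold lower (adjusted p = 0.037), being above background on 0 of 3 KO early arrays. All 4 of these named genes lie among the neighbours of Itpr2. The remaining 3 calls were transcripts without an established symbol, with ENSMUST00000111673 at least 2.41-fold, Gm7550 at least 2.71-fold and A_55_P2026049 2.42-fold higher in KO. They are named because the count is small, after their values were seen.

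The gene groups fixed in advance showed little at this stage. Ribosomal protein genes lay slightly higher in KO, 36 of 39 with a positive difference and a median of 0.10 (adjusted p = 0.0017), and so did genes of oxidative phosphorylation, the mitochondrial respiratory chain, 36 of 42 with a median of 0.092 (adjusted p = 0.011). Both calls were lost with an estimated correlation (adjusted p = 0.98 for each), and 0 members of either list passed on their own. Rpl35 had a log2 difference of 0.22 ± 0.10 and Ndufa4 of 0.32 ± 0.14 (adjusted p = 0.74 for each). Slide 1 had the largest medians, 0.29 for the ribosomal list against 0.046 and -0.049 on slides 2 and 3, and 0.23 for oxidative phosphorylation against 0.00098 and 0.050. Without KO early replicate 1 the adjusted p was 0.56 for the ribosomal list and 0.82 for oxidative phosphorylation. Quantile normalization gave 0.082 for both, and Xist as a covariate gave 0.053 for oxidative phosphorylation. The list of inositol trisphosphate receptors and calcium handling had 0 of 30 members past the threshold, over all genes and adjusted over the list alone, as did contacts between the endoplasmic reticulum and mitochondria with 0 of 19. Secreted factors of senescent cells had 0 of 40 and cyclin-dependent kinase inhibitors 0 of 8.

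In this comparison 1168 genes had an unadjusted p under 0.05, and 9.54% of all genes had groups that did not overlap, where chance gives 10%. The count of 7 fell to between 2 and 4 when any of the 6 arrays was left out, with 4 without WT early replicate 1, 3 without WT early replicate 2, 3 without WT early replicate 3, 2 without KO early replicate 1, 3 without KO early replicate 2 and 2 without KO early replicate 3. A replicate block gave 4, and the split of 5 higher and 2 lower was 3 and 2 after quantile normalization and 2 and 0 after normexp. Ints13 and Dera passed under the scalings, filters, replicate block and single arrays left out that were run for named genes, though 0 genes passed an unequal-variance test and 1 passed with only the 2 groups compared. Mgp had an adjusted p of up to 0.21 without KO early replicate 2 and Pbp2 of up to 0.29 without WT early replicate 3.

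**Figure D2:**
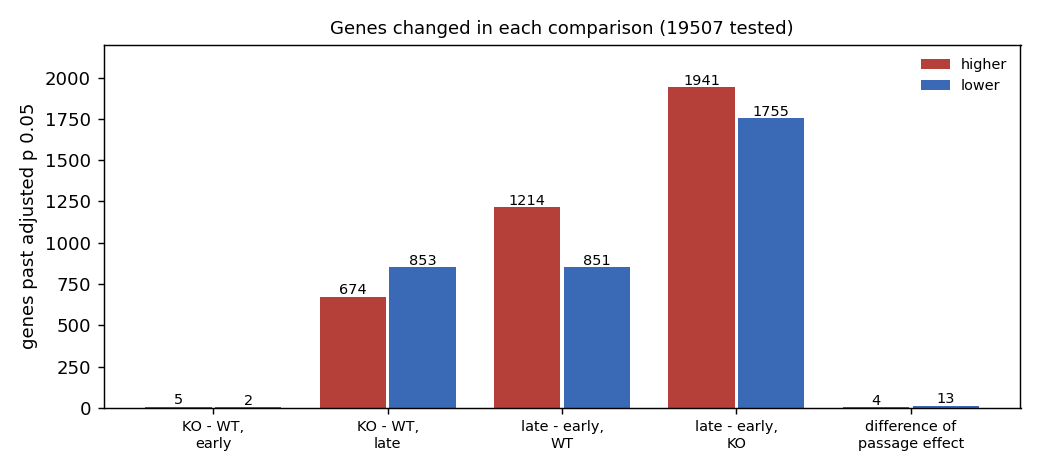
Number of genes past an adjusted p of 0.05 in each comparison, higher (red) and lower (blue), of 19507 genes tested. Both comparisons of passage and that of genotype at late passage held 1527 to 3696 changed genes, against 7 for genotype at early passage and 17 for the difference of passage effects.

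KO against WT at late passage asked the same of older cultures. Here 1527 genes differed, 674 higher and 853 lower in KO, and genes of cartilage and of the extracellular matrix were among the largest rises. Rises and falls in this comparison are differences of KO from WT, not changes with passage. Lum, the matrix proteoglycan lumican, was 11.7-fold higher in KO, a log2 difference of 3.55 ± 0.48 (SE, n = 3 per group, adjusted p = 0.0043). Col9a1, a collagen of cartilage, was 13.7-fold higher at 3.78 ± 0.62 (adjusted p = 0.0091), and Cnmd, chondromodulin of cartilage, was 49.5-fold higher at 5.63 ± 1.2 (adjusted p = 0.022). Slpi, a secreted protease inhibitor, rose by 4.37 ± 0.42 and Egfl6, a matrix protein with EGF-like repeats, by 4.56 ± 0.57. Egfl6 was above background on 1 of 3 WT late arrays and Cnmd on 2, so the sizes of their differences are uncertain. Epyc, the cartilage proteoglycan epiphycan, was at least 7.48-fold higher and Thbs4, thrombospondin 4, at least 14.9-fold higher, both being above background on 0 of 3 WT late arrays. Among the largest falls, Tnfsf18, a cytokine of the TNF family, had a log2 difference of -4.70 ± 0.79 and Vit, the matrix protein vitrin, of -4.04 ± 0.69. Tnfsf18 was above background on 1 of 3 KO late arrays and Vit on 2. Fgf1, a fibroblast growth factor, was at least 4.31-fold lower, Kprp, a keratinocyte protein, at least 5.25-fold lower, and Pbp2 at least 10.3-fold lower.

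Of 13 cartilage markers 6 rose and 0 fell, 7 and 0 adjusted over the list alone, with a median of 1.40 and medians of 1.12, 1.28 and 1.34 on the 3 slides (adjusted p = 3.1e-06, and adjusted p = 0.53 with an estimated correlation). Sox9, the transcription factor that directs cartilage formation, was 2.63-fold higher at 1.40 ± 0.15, and Hapln1, which links hyaluronan to proteoglycans, rose by 3.20 ± 0.40. In the extracellular matrix list 10 of 40 rose and 1 fell, 13 and 2 adjusted over the list alone, with a median of 0.34 (adjusted p = 4.8e-06, and adjusted p = 0.53 with an estimated correlation). Fbn2, fibrillin 2, was higher in KO by 1.78 ± 0.25, Col14a1, a fibril-associated collagen, by 2.00 ± 0.31 and Ogn, the proteoglycan osteoglycin, by 0.99 ± 0.16. With passage, the matrix list was called lower in WT and was not called in KO, as given below. Fibroblast markers were not called (adjusted p = 0.10), with 4 of 16 higher and 2 lower, 7 and 3 adjusted over the list alone. Among them Meox1, a mesodermal homeobox factor, rose by 1.86 ± 0.22.

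Macrophage markers were lower in KO, 0 of 18 higher and 2 lower over all genes, 0 and 14 adjusted over the list alone, with a median of -1.12 (adjusted p = 4.8e-06, and adjusted p = 0.53 with an estimated correlation). The medians were -0.58, -0.71 and -2.14 on slides 1, 2 and 3. Lyz2, lysozyme, had a log2 difference of -1.32 ± 0.33 and Cd68, a lysosomal protein of macrophages, of -1.43 ± 0.38. Without KO late replicate 3 the adjusted p of Lyz2 was 0.12 and that of Cd68 was 0.14. Skeletal muscle markers were not called (adjusted p = 0.21), with 0 of 9 higher and 1 lower, 2 and 3 adjusted over the list alone. The 1 lower was Des, desmin, at least 3.64-fold, with an adjusted p of 0.002, or 0.16 after normexp. Also not called were neural and glial markers, 1 of 10 higher and 2 lower (adjusted p = 0.29), epithelial, 0 of 9 and 2 (0.14), adipocyte, 1 of 7 and 2 (0.32), and endothelial markers, 1 of 6 and 0 (0.25).

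In the cholesterol biosynthesis list 0 of 24 rose and 4 fell, 0 and 11 adjusted over the list alone, with a median of -0.34 (adjusted p = 4.8e-06, and adjusted p = 0.53 with an estimated correlation). The slide medians were -0.54, -0.51 and -0.035. Msmo1, a sterol oxidase, had a difference of -0.84 ± 0.15 and Hsd17b7, a sterol reductase, of -0.68 ± 0.13. Of 34 p53 targets 0 rose and 6 fell, 1 and 14 adjusted over the list alone, with a median of -0.25 (adjusted p = 0.00017, and adjusted p = 0.53 with an estimated correlation). Dyrk3, a kinase, had -1.53 ± 0.23 and Pmaip1, the cell death protein Noxa, -1.28 ± 0.20, with Cdkn1a, the cell cycle inhibitor p21, at -0.66 ± 0.14 (adjusted p = 0.022). Genes of DNA replication and S phase had 0 of 42 past the threshold and 35 negative differences, with a median of -0.14 (adjusted p = 0.0019, and adjusted p = 0.60 with an estimated correlation). Genes of G2 and mitosis were not called (adjusted p = 0.91), with 19 of 41 positive differences, a median of -0.010 and slide medians of -0.14, -0.22 and 0.32. Oxidative phosphorylation had 0 of 42 past the threshold and 39 negative, with a median of -0.15 (adjusted p = 0.0018, and adjusted p = 0.61 with an estimated correlation). Ccne1, cyclin E, had -0.42 ± 0.12 (adjusted p = 0.067) and Cycs, cytochrome c, -0.41 ± 0.12 (adjusted p = 0.062), which passed after quantile normalization at 0.033.

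The interferon response list had 4 of 41 higher and 1 lower, 7 and 1 adjusted over the list alone, with a median of 0.24 and slide medians of 0.55, 0.17 and 0.042 (adjusted p = 0.0032, and adjusted p = 0.61 with an estimated correlation). Usp18, an interferon-induced protease, rose by 1.60 ± 0.26. Ribosomal protein genes had 38 of 39 positive differences with a median of 0.10 (adjusted p = 0.0019, and adjusted p = 0.61 with an estimated correlation), and quantile normalization gave 0.22. Secreted factors of senescent cells were not called as a group by camera at the preset correlation (adjusted p = 0.32). They had 2 of 40 higher and 5 lower, 3 and 8 adjusted over the list alone. Ccl2, a chemokine that recruits monocytes, was 2.57-fold lower at -1.36 ± 0.12 (adjusted p = 0.00084), Csf1, the macrophage growth factor, was lower at -0.69 ± 0.11, and Igfbp5, an insulin-like growth factor binding protein, rose by 2.32 ± 0.32. Inositol trisphosphate receptors and calcium handling were not called by camera at the preset correlation either (adjusted p = 0.19). This list had 2 of 30 higher and 3 lower, 2 and 7 adjusted over the list alone. Trpc6, a plasma membrane cation channel, was at least 1.95-fold lower, with an adjusted p of 0.0026, or 0.36 after normexp. Contacts between the endoplasmic reticulum and mitochondria had 0 of 19 past the threshold over all genes and adjusted over the list alone (adjusted p = 0.47), and cyclin-dependent kinase inhibitors had 1 of 8 higher and 1 lower, with a median of -0.014 and a mean of 0.030 (adjusted p = 0.91). Among stress genes Trib3, a pseudokinase induced in the integrated stress response, rose by 1.63 ± 0.14 and Slc7a11, the cystine transporter, by 1.39 ± 0.17. The unfolded protein response list was not called (adjusted p = 0.44), with 4 of 27 higher and 2 lower, 6 and 3 adjusted over the list alone, 14 negative differences, a median of -0.036 and a mean of 0.035. Antioxidant defence was not called (adjusted p = 0.29), with 5 of 34 higher and 2 lower, 6 and 7 adjusted over the list alone, 23 negative differences and a median of -0.15.

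At late passage 4864 genes had an unadjusted p under 0.05, and 39.3% of all genes had groups that did not overlap, where chance gives 10%. The split of 674 higher and 853 lower turned with the scaling, to 1016 and 782 after quantile normalization and 1020 and 766 after normexp. The count was 607 without WT late replicate 3, 255 without KO late replicate 1, 386 without KO late replicate 2 and 507 without KO late replicate 3, and it was 1 without both KO late arrays that carry Xist, where a lone KO late array was assumed to vary like the other groups. Of 59 genes followed through the settings 29 lost their call when 1 array was left out, among those named here Cnmd (adjusted p = 0.082), Cdkn1a (0.087), Msmo1 (0.062) and Hsd17b7 (0.064) without KO late replicate 1. The interferon list had an adjusted p of 0.19 without WT late replicate 1 and, without both arrays that carry Xist, 0.51, while S phase had 0.20 there. Of the 5 genes higher in KO at early passage 4 were again higher, against 0.173 for independent lists, and both lower genes were again lower, against 0.0875. WT arrays of the same number matched across passages, so the lists may not be independent and these values are no measure of chance. Across all genes the differences at the 2 passages correlated at 0.19, and genes are not independent replicates.

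**Figure D3:**
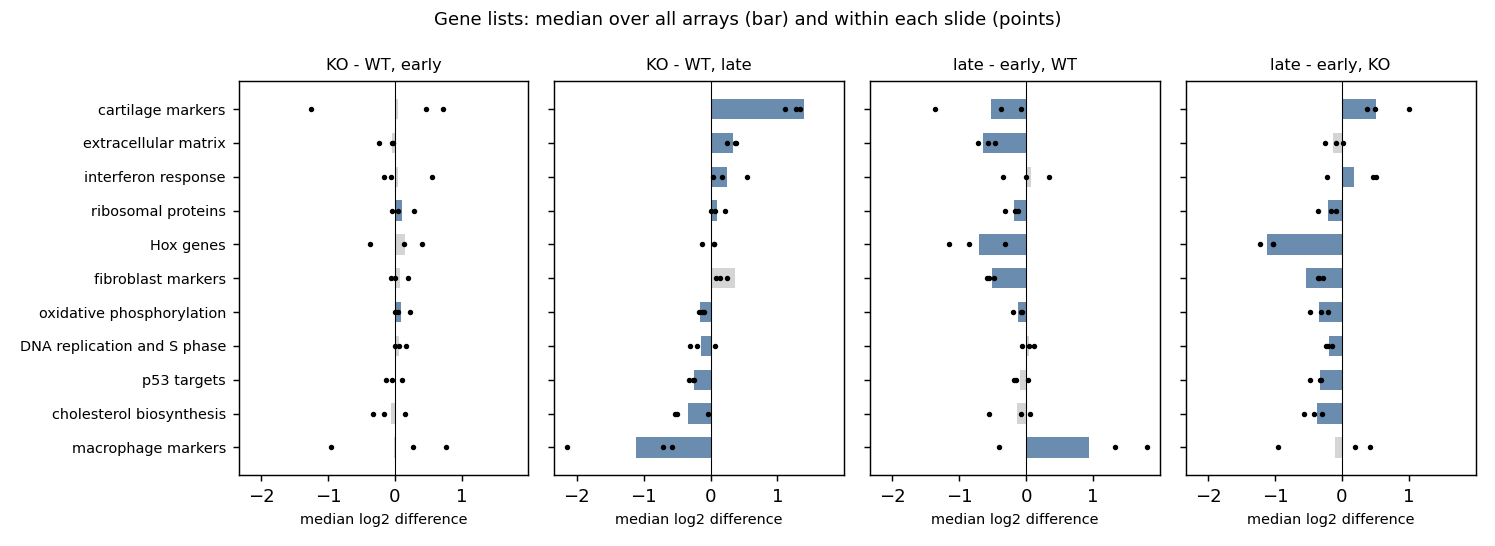
Median log2 difference of 11 gene lists in the 4 comparisons of groups (bars, blue where camera with a preset correlation called the list, grey otherwise), with the median within each of the 3 slides as points. Cartilage and matrix genes lie above 0 and macrophage, cholesterol and p53 genes below 0 for KO against WT at late passage on all 3 slides.

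Late against early passage in WT asked what 2 further passages do to normal fibroblasts. The comparison changed 2065 genes, 1214 higher and 851 lower. Igf2, insulin-like growth factor 2, was 15.6-fold lower at late passage, a log2 difference of -3.97 ± 0.32 (SE, n = 3 per group, adjusted p = 0.00044). Igfbp5 was 11.9-fold lower at -3.57 ± 0.32 (adjusted p = 0.00074), and Wt1, a transcription factor of embryonic mesenchyme, was lower at -3.43 ± 0.51. Sfrp2, a secreted Wnt modulator, had -3.54 ± 0.70 and Agtr1b, an angiotensin receptor, -3.95 ± 0.51. Wt1 and Agtr1b were each above background on 1 of 3 WT late arrays, so the sizes of their differences are uncertain. Dusp2, a phosphatase of MAP kinases, was 12.2-fold higher at 3.61 ± 0.57, and Egr4, a transcription factor induced by growth signals, was at least 9.55-fold higher, being above background on 0 of 3 early arrays. Pax8, a paired-box factor, rose by 3.32 ± 0.44.

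In the extracellular matrix list 0 of 40 rose and 17 fell, 0 and 24 adjusted over the list alone, with a median of -0.65 and slide medians of -0.47, -0.57 and -0.72 (adjusted p = 3.2e-10, and adjusted p = 0.096 with an estimated correlation). Thbs2, thrombospondin 2, had a log2 difference of -1.60 ± 0.20, Fbn2 of -1.65 ± 0.25, Col6a2 of -1.49 ± 0.25 and Lum of -2.85 ± 0.48. Of 16 fibroblast markers 0 rose and 6 fell, 0 and 8 adjusted over the list alone, with a median of -0.51 (adjusted p = 1.8e-05, and adjusted p = 0.096 with an estimated correlation). Meox1 had -2.25 ± 0.22 and Fap, a fibroblast surface protease, -2.16 ± 0.31. Of 31 Hox genes, which keep the positional identity of the embryo, 0 rose and 6 fell, 1 and 9 adjusted over the list alone, with a median of -0.71 (adjusted p = 0.00076, and adjusted p = 0.49 with an estimated correlation). Hoxa11 had -1.99 ± 0.28, Hoxa10 -1.29 ± 0.23 and Hoxa9 -1.24 ± 0.24. Skeletal muscle markers had 0 of 9 higher and 3 lower, 0 and 4 adjusted over the list alone, with a median of -0.53 (adjusted p = 0.034, and adjusted p = 0.50 with an estimated correlation), among them Des at -1.92 ± 0.31. Cartilage markers had 0 of 13 higher and 3 lower, 1 and 5 adjusted over the list alone, with a median of -0.53 and slide medians of -1.37, -0.082 and -0.38 (adjusted p = 0.032, and adjusted p = 0.62 with an estimated correlation). Comp, a cartilage matrix protein, had -2.17 ± 0.41.

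Secreted factors of senescent cells lay higher at late passage, 11 of 40 higher and 3 lower, 17 and 5 adjusted over the list alone, with a median of 0.51 and slide medians of 0.44, 0.43 and 0.47 (adjusted p = 0.0054, and adjusted p = 0.096 with an estimated correlation). Ereg, the growth factor epiregulin, rose by 1.74 ± 0.21, Spp1, osteopontin, by 1.70 ± 0.29 and Ccl2 by 1.09 ± 0.12. The cyclin-dependent kinase inhibitors, which rise in senescence in many cells, did not. Of the 8 measured 0 rose and 0 fell, with 7 negative differences and a median of -0.36 (adjusted p = 0.021, and adjusted p = 0.16 with an estimated correlation). Cdkn1a had -0.43 ± 0.14 (adjusted p = 0.077) and Cdkn2b, p15, -0.54 ± 0.18 (adjusted p = 0.088), which reached 0.0052 without WT late replicate 3. Macrophage markers were higher, 2 of 18 over all genes and 4 adjusted over the list alone with 0 lower, with a median of 0.94 (adjusted p = 0.00045, and adjusted p = 0.61 with an estimated correlation). Their slide medians were -0.41, 1.32 and 1.80. Lyz2 had a difference of 1.33 ± 0.33, with an adjusted p of 0.031, or 0.093 without WT late replicate 2.

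Smaller shifts touched several housekeeping groups. Ribosomal protein genes had 38 of 39 negative differences and 0 past the threshold, with a median of -0.18 (adjusted p = 2e-06, and adjusted p = 0.52 with an estimated correlation), and quantile normalization gave 0.73. Oxidative phosphorylation had 0 of 42 higher and 1 lower, with a median of -0.12 (adjusted p = 0.0015, and adjusted p = 0.62 with an estimated correlation). Genes of G2 and mitosis had 0 of 41 higher and 1 lower, with a median of -0.13 and slide medians of -0.075, 0.035 and -0.32 (adjusted p = 0.0086, and adjusted p = 0.69 with an estimated correlation). Single genes outside these groups included Trib3, lower at -1.20 ± 0.14, Mylk, the kinase of myosin light chain, lower at -1.54 ± 0.16, and Hk2, hexokinase 2, which rose by 0.97 ± 0.13.

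In WT 5543 genes had an unadjusted p under 0.05, and 27.7% of all genes had groups that did not overlap, where chance gives 10%. The count was 1298 without WT early replicate 2, 1167 without WT late replicate 1 and 1231 without WT late replicate 2, and the WT arrays alone with the replicate block gave 367. Single arrays ended the list calls of G2 and mitosis (adjusted p = 0.47 without WT late replicate 3), Hox genes (0.074 without WT early replicate 1), muscle (0.081 without WT late replicate 3) and cartilage (0.27 without WT early replicate 1). The calls of oxidative phosphorylation after quantile normalization (0.13) and of muscle in the authors' value table (0.48) were also lost.

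Late against early passage in KO asked the same of the KO-labelled cultures. It changed 3696 genes, 1941 higher and 1755 lower. All 3 KO early arrays were in the male range, while Xist was above background on KO late replicates 1 and 2. The early and late KO arrays may thus come partly from different embryos, which this comparison cannot separate from passage. Nr4a1, a nuclear receptor induced by growth signals, was 8.85-fold higher at late passage, a log2 difference of 3.15 ± 0.089 (SE, n = 3 per group, adjusted p = 9.7e-08). Egr4 was 22.5-fold higher at 4.49 ± 0.31 (adjusted p = 9.5e-05) and Cnmd 81.6-fold higher at 6.35 ± 1.2 (adjusted p = 0.0064). Egr4 was above background on 1 of 3 KO early arrays and Cnmd on 2, so both folds are uncertain. Pnoc, the precursor of the neuropeptide nociceptin, was at least 8.03-fold higher. Wt1 was at least 9.61-fold lower, Des at least 11.1-fold lower and Agtr1b at least 7.68-fold lower, each being above background on 0 of 3 late arrays. Klk8, a secreted protease, had -4.24 ± 0.44 and Megf10, a scavenger receptor of muscle precursors, -4.65 ± 0.77. Megf10 was above background on 1 of 3 KO late arrays.

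Of 42 genes of oxidative phosphorylation 0 rose and 22 fell, 0 and 32 adjusted over the list alone, with a median of -0.34 and slide medians of -0.48, -0.32 and -0.21 (adjusted p = 6.4e-11, and adjusted p = 0.32 with an estimated correlation). Cox5b, a cytochrome c oxidase subunit, had -0.54 ± 0.094, Ndufc1 of complex I -0.41 ± 0.078 and Sdhc of complex II -0.41 ± 0.080. In the cholesterol list 0 of 24 rose and 10 fell, 0 and 13 adjusted over the list alone, with a median of -0.38 (adjusted p = 3.6e-05, and adjusted p = 0.37 with an estimated correlation). Mvk, mevalonate kinase, had -0.68 ± 0.097, Fdps, farnesyl diphosphate synthase, -0.94 ± 0.14 and Nsdhl, a sterol dehydrogenase, -0.93 ± 0.14. Of 31 Hox genes 0 rose and 14 fell, 1 and 15 adjusted over the list alone, with a median of -1.12 and slide medians of -1.03, -1.03 and -1.23 (adjusted p = 0.00025, and adjusted p = 0.32 with an estimated correlation). Hoxa11 had -2.78 ± 0.28, Hoxb8 -2.15 ± 0.29 and Hoxa10 -1.65 ± 0.23.

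Of 34 p53 targets 2 rose and 12 fell, 3 and 19 adjusted over the list alone, with a median of -0.32 (adjusted p = 0.00023, and adjusted p = 0.32 with an estimated correlation). Bbc3, the cell death protein Puma, had -0.82 ± 0.14 and Cdkn1a -0.77 ± 0.14. Of the 8 cyclin-dependent kinase inhibitors 0 rose and 3 fell, 1 and 4 adjusted over the list alone, among them Cdkn2b at -1.27 ± 0.18 (adjusted p = 0.0021). This list was not called by camera at the preset correlation (adjusted p = 0.11). Genes of S phase had 0 of 42 higher and 6 lower, the same counts adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00082, and adjusted p = 0.55 with an estimated correlation), among them Rrm2, of ribonucleotide reductase, at -0.71 ± 0.14. Genes of G2 and mitosis had 0 of 41 higher and 1 lower, with a median of -0.23 (adjusted p = 0.00035, and adjusted p = 0.55 with an estimated correlation). Secreted factors of senescent cells had 9 of 40 higher and 5 lower, 10 and 6 adjusted over the list alone, and were not called (adjusted p = 0.35). Il6, the cytokine interleukin 6, rose by 1.86 ± 0.27 and Ereg by 1.41 ± 0.21, while Igfbp6, an insulin-like growth factor binding protein, had -3.73 ± 0.55.

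Contacts between the endoplasmic reticulum and mitochondria had 1 of 19 higher and 4 lower, the same counts adjusted over the list alone, with a median of -0.15 (adjusted p = 0.039, and adjusted p = 0.32 with an estimated correlation). Opa1, a mitochondrial fusion protein, had -0.33 ± 0.084 (adjusted p = 0.022) and Vapb, a tether of the endoplasmic reticulum, 1.04 ± 0.28 (adjusted p = 0.028). The highest adjusted p with 1 array left out was 0.088 for Opa1 without KO late replicate 3 and 0.10 for Vapb without KO early replicate 1. This list passed under few settings, with 0.084 without KO late replicate 2 and 0.16 after quantile normalization. Calcium handling had 1 of 30 higher and 6 lower, 2 and 6 adjusted over the list alone, with Trpc6 at least 4.68-fold lower. It was not called by camera at the preset correlation (adjusted p = 0.14). Antioxidant defence had 1 of 34 higher and 6 lower, with a median of -0.24 (adjusted p = 0.014, and adjusted p = 0.40 with an estimated correlation), among them Nqo1, a quinone reductase, at -1.71 ± 0.33.

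Cartilage markers had 3 of 13 higher and 0 lower, with a median of 0.52 (adjusted p = 0.014, and adjusted p = 0.55 with an estimated correlation), Sox9 rising by 0.79 ± 0.15. Fibroblast markers had 1 of 16 higher and 6 lower, 1 and 8 adjusted over the list alone, with a median of -0.54 (adjusted p = 0.034, and adjusted p = 0.34 with an estimated correlation), among them Prrx1, a mesenchymal homeobox factor, at -1.50 ± 0.25 and Thy1, a fibroblast surface protein, at -1.75 ± 0.31. Muscle markers had 0 of 9 higher and 2 lower, with a median of -0.36 (adjusted p = 0.014, and adjusted p = 0.32 with an estimated correlation). The interferon list had 6 of 41 higher and 0 lower, with a median of 0.18 and slide medians of 0.51, 0.46 and -0.23 (adjusted p = 0.014, and adjusted p = 0.68 with an estimated correlation), Ifi44, an interferon-induced protein, rising by 1.43 ± 0.29. Ribosomal protein genes had 0 of 39 higher and 1 lower, with a median of -0.21 (adjusted p = 0.00025, and adjusted p = 0.55 with an estimated correlation), and quantile normalization gave 0.78. Matrix genes had 2 of 40 higher and 4 lower (adjusted p = 0.45) and macrophage markers 0 of 18 either way (adjusted p = 0.76), so neither was called.

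In KO 6592 genes had an unadjusted p under 0.05, and 51.9% of all genes had groups that did not overlap, where chance gives 10%. The count was 1979 without KO early replicate 1, 2063 without KO early replicate 2, 1780 without KO late replicate 1, 2034 without KO late replicate 2 and 2210 without KO late replicate 3. With Xist as a covariate it was 2172, and without both KO late arrays that carry Xist it was 165. Among the lists, antioxidant defence had an adjusted p of 0.074 and cartilage of 0.079 without KO early replicate 1, fibroblast markers 0.10 without KO early replicate 3 and the interferon list 0.096 without KO late replicate 2. Without both arrays that carry Xist the interferon list had 0.49, G2 and mitosis 0.083 and 4 others 0.051, namely S phase, antioxidant defence, muscle and fibroblast markers. Muscle had 0.42 in the authors' value table.

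The passage changes of WT and KO, which share no array, had much in common. Of the genes higher at late passage 787 were shared, against 121 for independent lists, and of those lower 387 were shared, against 76.6, while 13 changed in opposite directions. Across genes the 2 passage effects correlated at 0.593, and genes are not independent replicates. Both lists of calls rest on the same pooled spread per gene, so they are not independent and these values are no measure of chance. Early and late arrays also held different positions on every slide, in both genotypes, which cannot be told apart from passage here.

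**Figure D4:**
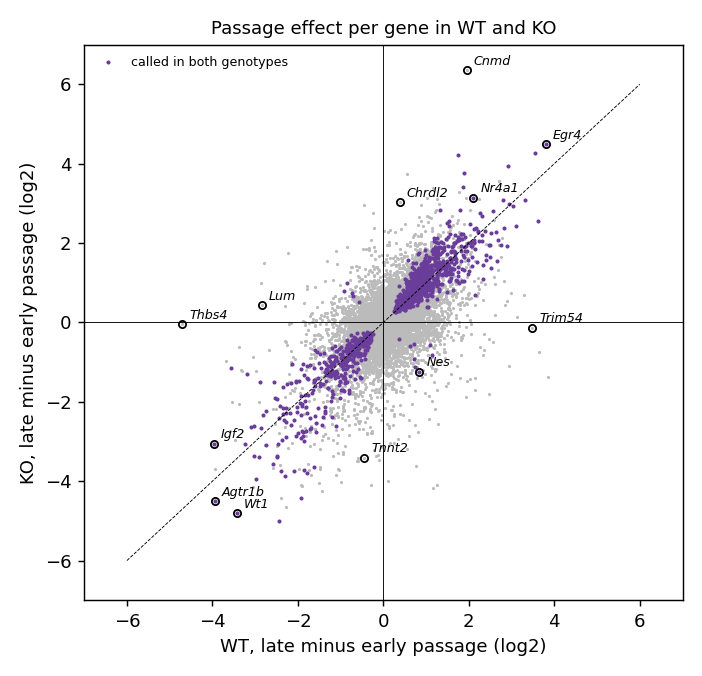
Log2 difference between late and early passage of each of 19507 genes in WT (horizontal axis) and KO (vertical axis), with genes called in both genotypes in purple and a dashed line where both effects are equal. Most points called in both lie near the line, while Thbs4 and Lum are low in WT alone and Cnmd and Chrdl2 are high in KO, of which Chrdl2 passed the test of the difference.

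Whether passage acts differently in KO-labelled cultures was tested as the difference between the KO and the WT passage effect. It held 17 genes, 4 with a higher and 13 with a lower effect in KO. Sex-linked genes matched between WT arrays of the same number but not between all such KO arrays. The KO effect may therefore include differences between embryos, which this test cannot separate from passage. Tnnt2, cardiac troponin T, had a difference of -2.96 ± 0.25 (SE, n = 3 per group, adjusted p = 0.0061), with a passage effect of -3.41 in KO and -0.45 in WT. Chrdl2, a chordin-like antagonist of bone morphogenetic proteins, had 2.65 ± 0.27 (adjusted p = 0.011), with a rise of at least 1.84-fold in KO and an effect of 0.38 in WT. As the bound shows, the 2.65 rests partly on signals not above background, and its size is uncertain. Ccl2 had -1.66 ± 0.18 (adjusted p = 0.011), being higher at late passage in WT and lower in KO. Trib3 had 1.56 ± 0.20 (adjusted p = 0.021), with -1.20 in WT and 0.37 in KO, and Nr4a1 had 1.04 ± 0.13 (adjusted p = 0.021). Nes, the intermediate filament protein nestin, had -2.08 ± 0.27 (adjusted p = 0.021).

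Among the lists, matrix genes had a median difference of 0.46 with slide medians of 0.52, 0.45 and 0.42 (adjusted p = 3.4e-08, and adjusted p = 0.49 with an estimated correlation), 0 of 40 past the threshold over all genes and 9 higher adjusted over the list alone. Cartilage markers had a median of 1.20, with slide medians of 1.90, 0.81 and 0.76 (adjusted p = 1.5e-06, and adjusted p = 0.56 with an estimated correlation), and 5 of 13 higher adjusted over the list alone. Lum had 3.29 ± 0.69 (adjusted p = 0.11) and Sox9 1.20 ± 0.21 (adjusted p = 0.085). Secreted factors of senescent cells were not called (adjusted p = 0.18, median -0.32), nor were calcium handling (adjusted p = 0.24), contacts between the endoplasmic reticulum and mitochondria (adjusted p = 0.57) or cyclin-dependent kinase inhibitors (adjusted p = 0.88).

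For the difference 2713 genes had an unadjusted p under 0.05. The replicate block gave 4 genes, and the split of 4 higher and 13 lower turned to 8 and 5 after quantile normalization and 11 and 7 after normexp. The count was 32 without WT early replicate 1, 11 without WT early replicate 2, 9 without KO early replicate 1, 1 without KO early replicate 2, 230 without KO early replicate 3, 42 without WT late replicate 1, 32 without WT late replicate 2, 1 without KO late replicate 1, 1 without KO late replicate 2 and 8 without KO late replicate 3. Of the 14 genes named by the rule, Tnnt2 alone passed under the scalings, filters, replicate block and single arrays left out that were run for them, while 0 genes passed without both KO late arrays that carry Xist. Without KO late replicate 1 the adjusted p was 0.070 for Chrdl2, 0.070 for Ccl2, 0.099 for Trib3 and 0.092 for Nr4a1, with 0.092 for Nes without KO late replicate 2.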

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

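Of the tests reported here, those of macrophages, sex and array position and the covariates were chosen after the results were seen.

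A test of the difference itself found 17 genes whose passage effect differed between KO and WT. Genes with a higher effect in KO were Chrdl2 (2.65), Trib3 (1.56), Fxyd6 (1.55) and Nr4a1 (1.04), as log2 differences of the effects with 3 arrays in each of the 4 groups. Fxyd6 encodes a regulator of the sodium pump. Genes with a lower effect in KO were the calcium-binding S100g (-3.73), the muscle ring finger gene Trim54 (-3.61), Fgf1 (-3.20), Tnnt2 (-2.96) and the nucleoporin-like Nup210l (-2.71). Slc22a23, a solute carrier, had -2.09, Nes -2.08, Dpyd, which breaks down pyrimidines, -1.87, Ccl2 -1.66 and Serpina9, a protease inhibitor, -1.63. The other 3 were Chst8 at -1.49 and the unnamed transcripts ENSMUST00000089450 at -1.45 and TC1625260 at -4.05, named after their values were seen. Trim54, Chrdl2, S100g, Fgf1 and Nup210l were above background on 0 of 3 arrays in at least 1 group, so their values rest partly on dim signals.

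Of the gene lists, 9 differed in their passage effect by camera with a preset correlation. Median differences were above 0 for cartilage markers (1.20), extracellular matrix (0.46) and interferon response (0.13). They were below 0 for macrophage markers (-1.08), p53 targets (-0.29), cholesterol biosynthesis (-0.28), antioxidant defence (-0.26), DNA replication and S phase (-0.25) and oxidative phosphorylation (-0.21). With an estimated correlation 0 of the 9 were called, with an adjusted p from 0.49 to 0.77. Single arrays ended 4 of these calls. The adjusted p was 0.051 for p53 targets without WT late replicate 3, 0.12 for antioxidant defence without KO early replicate 1, 0.38 for the interferon list without WT late replicate 1 and 0.057 for cholesterol without WT early replicate 1. Slide medians of the macrophage list were 0.47, -0.96 and -2.85, those of cholesterol -0.69, -0.31 and 0.11, and those of the interferon list 0.78, 0.31 and -0.21. Cartilage, matrix, p53, S phase, antioxidant and oxidative phosphorylation genes kept their sign on all 3 slides.

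In 8 of 100 drawn splits of genotype within passage, from 200 possible and with the real one included, the difference held at least as many genes as the real 17, so the splits do not exclude chance. The highest other split held 1460 genes. All 8 kept the late genotypes apart and so kept the late difference, while the 91 splits that mixed the late genotypes held 0 genes. The share is therefore no clean measure of chance, and the counts point to a structure of the late arrays. The passage effects differed mostly through KO against WT at late passage, where 1527 genes were called, against 7 at early passage.

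Fewer macrophages in the KO late cultures may be asked as a source of that late difference, since the mean of 18 macrophage markers was lower by -1.05 in KO late than in WT late arrays. Genes that follow macrophages should also follow that mean within the groups. The 851 genes called lower outside the list had a median share of -0.034 of their drop predicted from it within groups (95% interval -0.056 to -0.021 over 2000 resamplings of genes, which leaves out the spread between arrays), against 0.97 in the list itself. The share of the rise predicted in the 674 genes called higher was -0.096 (-0.12 to -0.081). Within groups, the median called gene outside the list thus did not follow the macrophage mean, in either direction. Genes were called only where their spread within groups was small, however, which favours genes that do not follow it. The 0.97 was taken over all 18 members of the list, called or not. The shares therefore cannot decide whether macrophages are a source of the late difference. With the mean as a covariate 480 of the 1527 genes were called again and all 1527 kept their direction. Their median absolute log2 difference was 0.89 before and 0.87 after, while the median SE went from 0.18 to 0.22.

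Sex of the cultures could be another source, as Xist was above background on 2 of 3 KO late arrays and 1 of 3 WT late arrays. With Xist as a covariate 1129 of the 1527 genes were called again and all 1527 kept their direction. Their median absolute log2 difference was 0.89 before and 0.88 after. Genes were called only where their spread within groups was small, which favours genes that do not follow Xist. These values therefore cannot decide how much sex contributed. All 1527 had late groups that did not overlap, although both groups held arrays with and without Xist. This argues against sex as the whole source of their difference. Position on the slide cannot be told apart from the groups, since 0 positions held more than 1 group. Genotype, macrophages and differences between embryos stay open beside it.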

How the results depend on the processing

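Chosen after the data were seen were gene-by-gene array weights, the covariates, leaving out both KO late arrays with Xist, the WT arrays alone, and leaving out arrays for the lists. Of 125 recounts of changed genes 58 stayed within 1.5 times the reported count and 67 did not. Of 1899 repeats for single genes 1683 kept direction and side of the threshold, 204 lost the call, 12 gained it and 0 reversed. These repeats covered only the scalings, the filters, the replicate block and the most extreme fits with 1 array left out. The unequal-variance test, the 2 groups alone, the covariates and the loss of both KO late arrays did not enter them. Genes named as the largest changes between 2 groups did not overlap between them. Leaving out 1 array could therefore not reverse these. Of 572 repeats for gene lists 448 kept the call, 124 lost it and 0 reversed. The estimated correlation ended all 44 list calls, fry 23, leaving out 1 array 16, quantile normalization 10, normexp 4, the strict filter 3 and a replicate block 0. Unless stated, the cause was not tested.

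The 7 genes of KO against WT at early passage became 2 with normexp, 4 with the authors' value table, 3 with no filter on dim probes, 4 with probes above background on all 12 arrays and 4 with a replicate block. They became 32 with array weights, 4 with the macrophage score as covariate, 1 without both KO late arrays that carry Xist, 1 with only the 2 groups compared and 0 with an unequal-variance test, where 1168 passed an unadjusted 0.05 in limma. With an array left out the count was 2 to 4.

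The 1527 genes of KO against WT at late passage became 615 with no filter, 5198 with array weights, 4212 with gene-by-gene weights, 578 with the macrophage score, 1 without both arrays that carry Xist, 35 with the unequal-variance test and 660 at a minimum of 2-fold, which only removes genes. With an array left out it was 255 to 1153.

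For passage in WT the 2065 genes became 1003 with no filter, 778 with the macrophage score, 849 without both arrays, 560 with only the 2 groups compared, 2 with the unequal-variance test, 367 with WT arrays only and a replicate block, and 803 at 2-fold. With an array left out it was 1167 to 2459. For passage in KO the 3696 genes became 2319 with no filter, 14728 with array weights, 13180 with gene-by-gene weights, 2172 with Xist as covariate, 165 without both arrays, 975 with the unequal-variance test and 1376 at 2-fold. With an array left out it was 1780 to 3884.

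The 17 genes of the difference became 9 with the authors' value table, 3 with no filter, 8 with the strict filter, 4 with a replicate block, 1399 with array weights, 385 with gene-by-gene weights, 6 with Xist as covariate and 0 without both arrays that carry Xist, where 2713 passed an unadjusted 0.05 in all 12 arrays. With an array left out it was 1 to 230. The replicate block called again 4 of the 7 early genes, 3 of the 17 and, elsewhere, 1226 of 1527, 1843 of 2065 and 3361 of 3696. Default array weights did not converge, with weights from 0.146 to 88.3. Leaving out both KO late arrays leaves a lone array assumed to vary like other groups. No filter, with 31978 genes tested in place of 19507, ended 45 single-gene calls, and normexp ended 28 against 11 for quantile normalization alone. Folds of genes at background on all arrays of a group are lower bounds only, and those at background on some arrays are uncertain.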

Other observations

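The lists and the tests of explanations in this part were chosen after the results were seen, except the splits of the arrays into other groups.

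Immediate-early genes, which growth factors and handling induce within minutes, were higher at late passage in both genotypes. In WT 18 of 28 rose and 0 fell, with a median of 0.94 (adjusted p = 6.3e-13, and 0.011 with an estimated correlation), and in KO 19 rose and 1 fell, with a median of 0.90 (adjusted p = 7.4e-12, and 0.011). Fos rose by 2.03 ± 0.25 in WT and 2.47 ± 0.25 in KO (SE, n = 3 per group), Egr1 by 1.63 ± 0.20 and 1.94 ± 0.20, Egr2 by 2.26 ± 0.23 and 2.77 ± 0.23, and Ptgs2, which makes prostaglandins, by 2.63 ± 0.35 and 2.27 ± 0.35. Klf4 was the gene that fell in KO, at -0.99 ± 0.21. The list was not called between KO and WT at early passage (adjusted p = 0.97) or late passage (0.56), nor in its passage effect (0.51). At late passage 3 members were higher and 1 lower in KO, among them Gem at 1.24 ± 0.18, Nr4a2 at 0.89 ± 0.098 and Dusp6 at -0.61 ± 0.13.

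Of 21 imprinted genes, expressed from a single parental copy, 0 were higher and 6 lower at late passage in WT, with a median of -0.23 (adjusted p = 0.0046, and 0.10 with an estimated correlation). H19, a non-coding RNA next to Igf2, had -1.65 ± 0.18 and Mest -1.47 ± 0.34. In KO 3 rose and 3 fell (adjusted p = 0.56). At late passage 4 were higher and 2 lower in KO than in WT, with a median of 0.40 (adjusted p = 0.030, and 0.19 with an estimated correlation), among them Zim1 at 2.73 ± 0.44, Peg3 at 1.97 ± 0.33 and H19 at 1.06 ± 0.18. Of 12 complement genes 4 were higher and 1 lower in KO at late passage, with a median of 0.65 (adjusted p = 0.0046, and 0.51 with an estimated correlation). C4b had 2.67 ± 0.43, C1ra 1.41 ± 0.20 and C2 -1.51 ± 0.39. The difference of passage effects was called for imprinted genes (median 0.53, adjusted p = 0.011, and 0.14 with an estimated correlation) and complement genes (median 0.46, adjusted p = 0.010, and 0.53), with 0 of 21 and 0 of 12 members past the threshold. In all, 15 tests were adjusted together.

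Of the lists fixed beforehand, 11 were called in 0 of the 5 contrasts by camera at the preset correlation, the only test given for them here. The adjusted p ran from 0.14 for calcium handling, 0.095 for the unfolded protein response, 0.051 for the contractile and TGF-beta list, 0.14 for glycolysis, 0.092 for genes near Itpr2 and 0.17 for sex-linked genes up to 1. For markers of other cell types its lowest value was 0.24 in endothelial, 0.14 in epithelial, 0.11 in neural and glial, 0.80 in erythroid and 0.31 in adipocyte markers.

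Genes near Itpr2 differed between KO and WT at both passages. Of 122 measured neighbours, 100 before and 22 after the gene, 9 had p under 0.01 in the same direction at both passages, or 7.38%, against 26 of 14454 other genes, or 0.18% (odds ratio 44.1, two-sided Fisher exact p = 8.8e-12). They were Ints13 (0.80 at early and 0.78 at late passage), Stk38l (0.61 and 0.63), Rep15 (-0.45 and -0.50), Mgst1 (0.55 and 0.61), Dera (1.14 and 1.14), Mgp (-1.06 and -0.61), BC049715 (2.30 and 1.77), Gprc5a (-0.75 and -1.57) and Pbp2, and windows of 200 genes that held none of the 122 neighbours had at most 2. A chromosome segment of another strain carried along with the targeted allele may explain the 9 genes, and the count met what it needs. A sequence variant under the probe stays open for the 6 genes with 1 kept probe, and in the 3 genes with several, BC049715, Mgst1 and Stk38l, all 3 showed the difference on at least 2 probes, which argues against it there.

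Sex-linked genes differed between KO arrays of the same number. Ddx3y was below background on KO late replicate 2, and the difference from KO early replicate 2 was -7.20 or more negative, taken at the lowest signal above background. This argues against a single culture grown to both passages there. WT pairs 2 and 3 differed by -0.0058 and 0.064, and pair 1 was below background at both passages. For a swap between KO and WT, 10 genes near Itpr2 were chosen from the 6 early arrays alone, and 0 of the 6 late arrays lay nearer the other genotype in their median position, set to 0 at WT early and 1 at KO early. The lowest KO late array had 0.76 and the highest WT late array -0.016, which argues against a swap. Without Ints13 and Dera, KO late replicates 1 and 2 had 0.47 and 0.39, slightly nearer WT, while the highest WT late array had -0.031, so no WT array was out of place as a partner. In KO late replicate 1 Ddx3y lay -0.90 from the lowest male array with Xist above background, values that male and female cells mixed in that culture would need. No biological explanation was tested.

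The 6 arrays of each 2-group comparison make 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, was as large. For KO against WT the real split gave 7 genes and the highest other 4 at early passage, and 1527 and 0 at late passage. For passage the values were 2065 and 3 in WT and 3696 and 0 in KO.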
